A study of Mus musculus with 8 samples.

How the data were processed

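Messenger RNA of osteoblasts from female Col2.3-GFP mice was measured by RNA-seq. In these mice green fluorescent protein is driven by a fragment of the Col1a1 promoter that is active in bone-forming cells. Per the labels' protocols, young adult mice received 4 intravenous injections of doxorubicin at 5 mg/kg, or of phosphate-buffered saline (PBS), at intervals of 1 week, and tissue was taken 8 weeks after treatment. Marrow was removed by centrifugation, bone chips were digested with enzymes, and GFP-positive cells were sorted into lysis buffer. RNA was extracted with a column kit for small samples, and cDNA was made with the SMART-Seq v4 Plus kit, which amplifies full-length cDNA by PCR from little RNA and does not mark the strand. No molecular identifiers are named in the protocols, so all counting intervals and floors given here cover counting error only.

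The deposited table holds raw read counts per gene symbol for 21154 genes, with 1 column per library and none pooled. Per the submitters' processing notes, the tools were FastQC 0.11.5, MultiQC 1.7, Trim Galore 0.6.6, STAR 2.7.9a, SAMtools 1.17 and featureCounts 2.0.1, with the mouse build GRCm39. The annotation, the strand setting and the handling of reads that match several genes are not given in the sources used here. The smallest total of a gene over the libraries was 10 counts, so a filter on low totals had been applied before deposit; that filter is not given in the sources used here. All rows named a gene. No coordinates are given, because the annotation of the build used by the authors was not used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and counts of near-identical genes (histocompatibility genes, hemoglobin genes, ribosomal protein genes with processed pseudogenes, immunoglobulin segments) are uncertain.

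Groups were taken from the sample titles: 3 PBS libraries and 5 doxorubicin (DOX) libraries. The titles call them biological replicates. The labels also give a batch. Batch 1 held PBS replicate 1 and DOX replicates 1 and 2, and batch 2 held the other libraries. For DOX replicate 1 the labels disagree: its title says DOX and its treatment tag says PBS. Its library name holds the letter D, as do those of the other DOX libraries and of no PBS library. It was counted as doxorubicin, and the comparison was repeated without it and with it counted as PBS. Replicate numbers 1 to 3 were shared between the groups, but no label ties them to a shared litter or day. With the replicate number as a block, DOX replicates 4 and 5 have no PBS partner and add nothing to the group difference. That difference then rests on replicates 1 to 3, and replicate 2 sets a DOX library of batch 1 against a PBS library of batch 2.

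Library totals ran from 39419027 to 44299591 counts. The counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and the plots were drawn with Python 3.11.15 and matplotlib 3.10.9. The main test was edgeR's quasi-likelihood test with TMM scaling, the filterByExpr filter (15373 genes kept) and batch and group as terms. It was two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors were derived from the fold change and the F statistic. CPM values are counts scaled by the TMM-adjusted library sizes, and log2 CPM values carry a prior count of 2. Before the data were examined, 49 gene lists were fixed: pathways, bone and marrow cell types, other cell types that the sort could hold, and a check of sex-linked genes. The 47 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and limma's fry were run as alternatives. The mast cell, basophil and eosinophil list had 4 tested members and no test over all libraries. With 5 tested members under some other settings it was tested, and it passed as lower without PBS replicate 1 (adjusted p = 0.020), without PBS replicate 2 (0.0428), with no filter (0.00173) and without PBS replicate 1 and DOX replicate 1 together (0.0491). The numbers of lists called under those settings include it. List scores are the mean log2 CPM of the tested members in a library, and they were compared by exact two-sided permutation over the 56 ways to choose 3 of the 8 libraries. The smallest p this design allows is 0.0179. These 56 ways exchange labels between batches, so list p-values and counts of calls were also set against the 30 ways that keep the number of PBS libraries in each batch, where the smallest share is 0.0333.

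The genes named were set before the data were examined. They are the genes past the threshold in each direction or, where fewer than 5 passed, the genes of smallest p up to 8 per direction with a mean of at least 1 log2 CPM. Gene models without a standard symbol and immunoglobulin and T cell receptor segments were left out. A fixed panel of 13 genes was added, and from each list up to 2 members that passed when adjusted over the list alone, or otherwise the member with the highest mean. One gene that the rule selects is not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

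The alternatives set before the data were examined were DESeq2, limma-voom with quality weights, edgeR's robust fit, DESeq2 size factors, scaling by library size alone, no filter and a stricter filter on low counts, no batch term, batch 2 alone, the replicate number as a block, DOX replicate 1 counted as PBS, each library left out in turn, a 2-fold minimum and a threshold of 0.10. Alternatives chosen after seeing the data were leaving out PBS replicate 1 and DOX replicate 1 together, DESeq2 on the filtered genes, a correction of the list tests for transcript length and GC content, and the share of counts from Col1a1 and Col1a2 as a term in place of batch. Length and GC came from reference transcripts matched by symbol, which were found for 97.8% of the tested genes. No pair of libraries agreed within sampling noise: the closest pair, PBS replicates 2 and 3, had a chi-square per degree of freedom of 27.9.

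The tests were checked on counts simulated for the DOX against PBS comparison, from the means and library sizes of these libraries. In the simulation 50 genes were changed at each fold, and the filter used for edgeR kept 14568 genes. EdgeR recovered 8% of genes changed 1.5-fold, 72% of those changed 2-fold, 96% of those changed 4-fold and 100% of those changed 8-fold, with 5 false calls. DESeq2, run without that filter and so on more genes, recovered 22%, 80%, 98% and 100% with 36 false calls. All changed genes had a mean above 1 log2 CPM, and they were changed together with a shifted list, which eases the adjusted threshold. The simulated genes vary independently within a group. The rates may therefore be lower in the real libraries, where Mstn, with a log2 fold change of 5.95, did not pass in edgeR. A lack of calls does not exclude large changes. For a list shifted by 0.3 log2 units, camera gave an adjusted p of 0.00161 at the preset correlation and 0.192 with an estimated correlation.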

Results

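The data describe what sorted mouse osteoblasts expressed 8 weeks after a course of doxorubicin, an anthracycline that damages DNA and is used in chemotherapy. The series addresses the effect of chemotherapy on cells of the skeleton. Osteoblasts, the cells that lay down bone matrix, were compared between 3 PBS and 5 doxorubicin (DOX) libraries from female mice. The library titled DOX replicate 1 carried a treatment tag of PBS, so each result below also rests on that library's title. Library totals ran from 40985302 to 44299591 counts in PBS (n = 3) and from 39419027 to 44151882 in DOX (n = 5).

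All 8 libraries had the profile of matrix-producing osteoblasts. Col1a1 and Col1a2, which encode the chains of type I collagen, together took 32.4 ± 11.5% of counts in PBS (SD, n = 3) and 29.3 ± 5.16% in DOX (SD, n = 5; exact permutation p = 0.625). Bglap, which encodes osteocalcin, stood at 19344 ± 5720 CPM in PBS and 19359 ± 2077 CPM in DOX. The libraries differed more from each other than the groups did. In PBS replicate 1 the collagen share was 19.1%, against 39.5% and 38.7% in the other PBS libraries, and in DOX replicate 1 it was 23.2%. Spp1, which encodes the matrix protein osteopontin, took 2.88% of counts in PBS replicate 1 and between 0.344% and 1.03% in the other 7 libraries. Hemoglobin genes took 0.0167% in PBS replicate 1 and 0.0120% in DOX replicate 1, and at most 0.00283% elsewhere. The first principal component, with 32.9% of the variance of log2 CPM, put these 2 libraries at the low end (-71.9 and -62.8). PBS replicate 3 lay at its high end (75.9). On the second component, with 18.2%, PBS replicate 1 (-56.6) and DOX replicate 1 (72.9) lay at opposite ends. The number of detected genes was 18089 ± 737 in PBS (SD, n = 3) and 18838 ± 364 in DOX (SD, n = 5; exact permutation p = 0.0893).

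**Figure D1:**
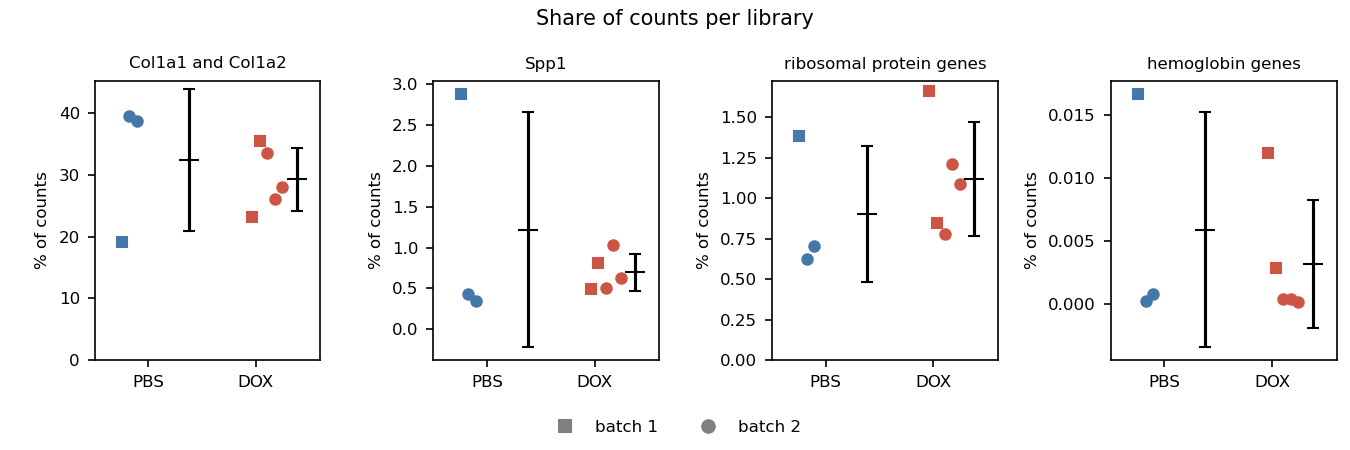
Percent of counts per library (y axis) for type I collagen, Spp1, ribosomal protein and hemoglobin genes in PBS (n = 3) and DOX (n = 5); squares are batch 1, circles batch 2, and bars show the mean ± SD. PBS replicate 1, the PBS square, had the lowest collagen share, 19.1%, and the highest Spp1 share, 2.88%.

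No gene passed the threshold between DOX and PBS osteoblasts in the main test. EdgeR's quasi-likelihood test called 0 of 15373 genes, and its smallest adjusted p was 0.995. At an unadjusted p under 0.05 it listed 571 genes, 304 higher and 267 lower, which is 3.71% of those tested. Limma-voom with quality weights also called 0 genes, with 1565 at an unadjusted p under 0.05. DESeq2 called 26 of the genes in the table (18 higher, 8 lower) and, on the genes that edgeR tested, 15 higher and 0 lower. Of the 8 lower genes in DESeq2, 7 were detected in 1 library alone. Of the 56 ways to label 3 libraries PBS, 20 gave at least 15 genes in DESeq2, the real one included. EdgeR called 0 genes without DOX replicate 1 and 0 with it counted as PBS.

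Among the higher genes, Mstn and Kera went from nearly no counts in PBS to counts in each DOX library. Neither they nor the other genes of this paragraph passed in edgeR, where all had an adjusted p of 0.995. Mstn, which encodes the growth inhibitor myostatin, had 6 counts over the PBS libraries and 708 over the DOX libraries, with a log2 fold change of 5.95 ± 1.03 (SE). Kera, which encodes the proteoglycan keratocan, had 3 and 502 counts, a ratio of 97.4 with a counting interval of 33.1 to 474. All PBS counts of both genes came from PBS replicate 2, so the size of both fold changes rests on that library. All 5 DOX libraries lay above every PBS library for both genes, at 3.19 ± 1.66 CPM for Mstn and 2.30 ± 1.09 CPM for Kera (SD, n = 5). Angptl7, which encodes a secreted angiopoietin-like protein, had a log2 fold change of 2.65 ± 0.63 (SE), with 3 of 5 DOX libraries above every PBS library. Tnmd, which encodes the tendon protein tenomodulin and was chosen after its values were seen, stood at 4.02 ± 1.58 CPM in PBS (SD, n = 3) and 12.7 ± 5.91 CPM in DOX (SD, n = 5). DESeq2 called Mstn (adjusted p = 3.2e-08), Kera (adjusted p = 9.33e-07) and Tnmd (adjusted p = 0.0265), and did not call Angptl7 (adjusted p = 0.745).

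Further genes had a small unadjusted p in edgeR. Txnip, which encodes a thioredoxin-binding protein that restrains glucose uptake, stood at 226 ± 48.7 CPM in PBS (SD, n = 3) and 322 ± 38.6 CPM in DOX (SD, n = 5). Its log2 fold change was 0.55 ± 0.12 (SE), with all 5 DOX libraries above every PBS library (adjusted p = 0.995 in edgeR, 0.0018 in DESeq2). Nnmt, which encodes nicotinamide N-methyltransferase, stood at 12.1 ± 4.11 and 42.2 ± 24.3 CPM, with a log2 fold change of 1.79 ± 0.40 (SE) and an adjusted p of 0.000821 in DESeq2. The cation channel gene Trpc6 had a log2 fold change of 1.12 ± 0.27 (SE), Adam23 of 1.22 ± 0.28, Fam219b of 0.86 ± 0.19 and Ttc30b of 0.73 ± 0.18. DESeq2 called Trpc6, Adam23 and Fam219b and did not call Ttc30b. Among the lower genes, the values were -0.56 ± 0.14 for the metalloprotease gene Adamts12, -0.63 ± 0.17 for Gnptab, which acts in targeting enzymes to lysosomes, and -1.05 ± 0.29 for B3gnt7. Nckipsd, Klhl42, Kif16b and Tmx3 lay between -0.67 and -0.50. No test used here called any of these 7 lower genes.

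**Figure D2:**
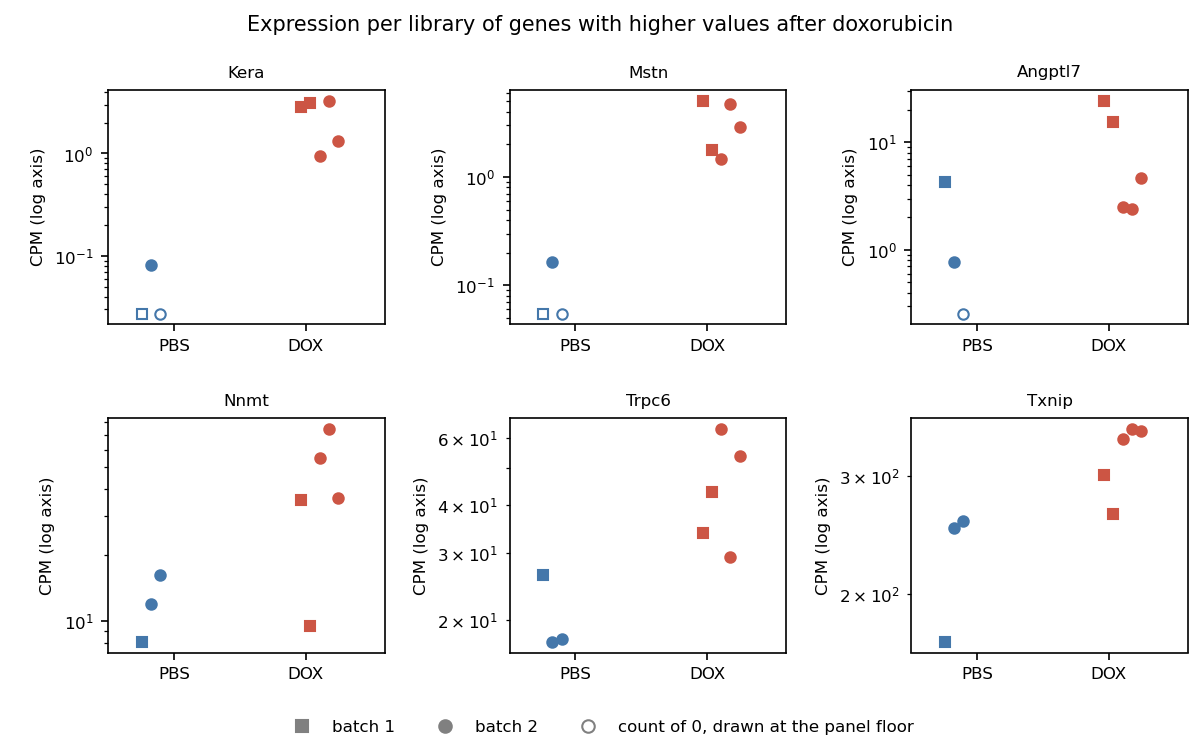
CPM per library on a log axis for Kera, Mstn, Angptl7, Nnmt, Trpc6 and Txnip in PBS (n = 3) and DOX (n = 5); squares are batch 1, circles batch 2, and open symbols are counts of 0 drawn at the panel floor. The DOX libraries lie above every PBS library in 5 of 5 cases for Kera, Mstn, Trpc6 and Txnip and in 4 of 5 for Nnmt.

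Markers of osteoblast identity and maturation showed no difference that passed the main test. The log2 fold change was -0.19 ± 0.36 (SE) for Col1a1, 0.06 ± 0.16 for Bglap, -0.10 ± 0.17 for Alpl (alkaline phosphatase), -0.03 ± 0.17 for Sp7 and -0.18 ± 0.15 for Runx2, both transcription factors of the osteoblast lineage. The 95% interval for Runx2 was -0.51 to 0.15. Of the osteoblast matrix and mineralisation list 13 of 30 members were higher and 17 lower, with a median of -0.06 and the camera test in the upward direction (adjusted p = 0.787). The call and direction changed without PBS replicate 1, where the list passed as lower (adjusted p = 0.00263, median -0.12), and in batch 2 alone (adjusted p = 0.000391, median -0.12). The osteocyte list, for cells embedded in bone, had 12 of 19 members higher (adjusted p = 0.57) and passed as higher with DOX replicate 1 counted as PBS (adjusted p = 0.0207), and Dmp1, an osteocyte gene, had a log2 fold change of 0.17 ± 0.21 (SE). The direction turned between batches for several genes. Col1a1 differed by 0.85 within batch 1 and by -0.74 within batch 2, and Spp1 by -1.92 and 0.56 on the log2 scale.

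Genes of the response to DNA damage showed no difference that passed the main test. Cdkn1a, a p53 target that encodes the cell cycle inhibitor p21, stood at 285 ± 28.7 CPM in PBS (SD, n = 3) and 291 ± 39.4 CPM in DOX (SD, n = 5), with a 95% interval of -0.24 to 0.32 for its log2 fold change. Mdm2, which encodes the ubiquitin ligase of p53, had a log2 fold change of -0.04 ± 0.12 (SE), with an interval of -0.31 to 0.22. Of the p53 target list 18 of 35 members were higher (camera adjusted p = 0.758). The senescence list had 16 of 25 members higher (adjusted p = 0.962), the DNA repair list 16 of 41 (adjusted p = 0.57) and the cell cycle list 31 of 44 (adjusted p = 0.184). The senescence list passed as higher without PBS replicate 1 (adjusted p = 4.94e-05, median 0.56) and in batch 2 alone (adjusted p = 4.87e-05, median 0.47). The cell cycle list passed as higher without PBS replicate 1 (adjusted p = 0.00263), PBS replicate 2 (0.00266) or DOX replicate 1 (0.0496), in batch 2 alone (0.00386) and with DOX replicate 1 counted as PBS (0.00781). The p53 target and DNA repair lists passed under no setting. Mki67, a marker of dividing cells, stood at 6.75 ± 2.96 CPM in PBS and 5.39 ± 0.484 CPM in DOX. No member of these 4 lists passed in edgeR, either over all genes or adjusted over the list alone.

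Factors through which osteoblasts act on other cells varied between libraries. Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, had a log2 fold change of -0.11 ± 0.53 (SE), and Tnfrsf11b, its decoy receptor osteoprotegerin, of -0.54 ± 0.40. Cxcl12, a chemokine that retains blood stem cells in marrow, had a value of 0.41 ± 0.49. Within batches the difference for Cxcl12 was -0.74 in batch 1 and 1.02 in batch 2, for Tnfsf11 it was -1.52 and 1.01, and for Tnfrsf11b it was -1.96 and 0.38. Tnfrsf11b stood at 112 CPM in PBS replicate 1, against 21.7 and 26.2 CPM in the other PBS libraries, and without that library its log2 fold change was 0.39. The list of factors of the haematopoietic niche had 7 of 20 members higher (camera adjusted p = 0.83), and that of osteoclast-regulating factors 5 of 13 (adjusted p = 0.106). The list of CXCL12-abundant reticular cells and skeletal progenitors had 11 of 24 members higher (adjusted p = 0.57), with a negative median, a positive mean and a downward test. Both the niche and the reticular cell list passed in opposite directions depending on the libraries. Without PBS replicate 1 they passed as higher (adjusted p = 0.00373 and 0.00791), as in batch 2 alone (0.00386 and 0.0317), and without PBS replicate 3 they passed as lower (0.010 and 0.00166). The niche list also passed as higher with DOX replicate 1 counted as PBS (0.0399). The list of osteoclast-regulating factors passed as lower without DOX replicate 2 (0.0300) or DOX replicate 3 (0.0477).

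At the level of gene lists, 8 of 47 passed in camera with the preset correlation, 6 higher and 2 lower. None of the 47 passed with an estimated correlation, where the adjusted p of the 8 lists was 0.904 or 0.941, and none passed in fry (adjusted p = 0.976). Of the 56 ways to label 3 of the 8 libraries PBS, between 7 and 35 gave a list p as small as the real one, depending on the list. The calls below are therefore those of the preset correlation alone. Camera called 16 lists without PBS replicate 1 and DOX replicate 1 together, 14 without PBS replicate 2, 15 without PBS replicate 3, 13 without DOX replicate 3 and 18 with DOX replicate 1 counted as PBS. Of the 39 lists not called, 27 passed under at least 1 other setting, 5 of them in both directions.

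Genes of protein synthesis and respiration rose together by camera's preset test, by small amounts. All 79 tested ribosomal protein genes were higher in DOX, with a median log2 fold change of 0.25 (adjusted p = 6.59e-17 in camera; adjusted p = 0.904 with an estimated correlation). None passed singly, and Rplp0, the one with the highest mean, had a value of 0.18 ± 0.15 (SE). Of the genes encoded in the nucleus for oxidative phosphorylation 72 of 73 were higher, with a median of 0.19 (adjusted p = 1.14e-12; 0.904 with an estimated correlation). The mean score of the ribosomal list differed by 0.05 within batch 1 and 0.35 within batch 2, and that of oxidative phosphorylation by 0.02 and 0.27. The medians depended on single libraries. In voom the ribosomal median was 0.23, against 0.14 without PBS replicate 2 and 0.08 with DOX replicate 1 counted as PBS. For oxidative phosphorylation it was 0.18, against 0.12 without PBS replicate 2, 0.07 with DOX replicate 1 counted as PBS and 0.29 without PBS replicate 1. A correction for transcript length and GC content, chosen after seeing the data, took the medians from 0.23 to 0.09 and from 0.18 to 0.05. Ribosomal protein genes took 1.38% of counts in PBS replicate 1, against 0.621% and 0.702% in the other PBS libraries, and 1.67% in DOX replicate 1. The difference in score over all libraries had an exact permutation p of 0.214 for ribosomal proteins and 0.179 for oxidative phosphorylation.

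Genes induced by interferon also rose by camera's preset test. Of the interferon response list 40 of 46 members were higher, with a median log2 fold change of 0.39 (adjusted p = 2.96e-11; adjusted p = 0.904 with an estimated correlation), and 13 had an unadjusted p under 0.05 in edgeR. No member passed over all genes or adjusted over the list alone. The antigen presentation list had 21 of 24 members higher, with a median of 0.23 (adjusted p = 1.11e-05; 0.904 with an estimated correlation). B2m, the light chain of class I histocompatibility molecules and the member with the highest mean of both lists, stood at 2307 ± 775 CPM in PBS (SD, n = 3) and 2755 ± 506 CPM in DOX (SD, n = 5). Genes chosen after their values were seen were Isg15, with a log2 fold change of 1.05 ± 0.33 (SE), Ifit3 with 1.42 ± 0.43, Irf7 with 0.87 ± 0.28 and Irf1 with 0.68 ± 0.18. The interferon score was higher in DOX by 0.23 within batch 1 and 0.59 within batch 2, and 2 of 5 DOX libraries lay above every PBS library (exact permutation p = 0.214). The median of the interferon list, 0.37 in voom, was 0.24 without PBS replicate 2 and 0.14 with the replicate number as a block (adjusted p = 0.0353). It was largest without PBS replicate 1 (0.53) and in batch 2 alone (0.52), where the neutrophil and the monocyte and macrophage lists also passed as higher. With the replicate number as a block the antigen presentation list no longer passed (adjusted p = 0.322).

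Immediate early genes, which respond within minutes to stimuli and to cell handling, rose by camera's preset test with 23 of 28 members higher and a median of 0.29 (adjusted p = 5.1e-06; adjusted p = 0.904 with an estimated correlation). Ccn1, the member with the highest mean, had a log2 fold change of 0.21 ± 0.16 (SE). The median of the immediate early list, 0.26 in voom, was 0.56 with the replicate number as a block. In that fit the group difference rests on replicates 1 to 3, and replicate 2 sets batch 1 against batch 2. The call was lost when DOX replicate 1 was counted as PBS (voom median 0.07, adjusted p = 0.169). The fibroblast, periosteum and tendon list rose with 20 of 30 members higher and a median of 0.14 (adjusted p = 0.0305; 0.904 with an estimated correlation), and 3 members, Kera, Angptl7 and Tnmd, passed when adjusted over the list alone. Its score differed by 0.03 within batch 1 and 1.06 within batch 2. This call was lost without PBS replicate 3 (adjusted p = 0.544), without DOX replicate 2 (0.195), without DOX replicate 5 (0.209) and with a stricter filter (0.138). It was also lost with the replicate number as a block (0.142) and with the collagen share as a term, chosen after seeing the data (0.0987). The median of the list, 0.06 in voom, ran from 0.00319 without PBS replicate 3 to 0.79 without PBS replicate 1 when 1 library was left out, and was 0.84 in batch 2 alone.

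Both lists that fell by camera's preset test were of other cell types and rested on batch 1. The erythroid list had 19 of 26 members lower, with a median of -0.40 in edgeR and -0.94 in voom (adjusted p = 1.84e-11, and 0.904 with an estimated correlation). Without DOX replicate 2 the list had a voom median of -0.39. Its score differed by -1.28 within batch 1 and 0.06 within batch 2, and without PBS replicate 1, the library with the highest hemoglobin share, the adjusted p was 0.867. The endothelial list had 13 of 22 members lower, with a median of -0.04 in edgeR and -0.56 in voom (adjusted p = 0.0133; 0.941 with an estimated correlation). The call was lost with no batch term (voom median -0.08, adjusted p = 0.484) and with the replicate number as a block (-0.15, adjusted p = 0.93). Its direction reversed in voom without PBS replicate 1 (median 0.12, adjusted p = 0.925), without DOX replicate 1 (0.29, adjusted p = 0.398) and in batch 2 alone (0.051, adjusted p = 0.924). With DOX replicate 1 counted as PBS the list passed as higher (0.53, adjusted p = 0.00315). Lists of several other cell types did not pass in the main test, where the adjusted p was 0.0602 for B cells and plasma cells, 0.57 for T and NK cells, 0.83 for neutrophils, 0.787 for monocytes and macrophages, 0.184 for osteoclasts and 0.944 for skeletal muscle. Ighm, the B cell gene with the highest mean, stood at 4.66, 15.1 and 393 CPM in PBS replicates 1 to 3 and at 14.7 ± 9.51 CPM in DOX (SD, n = 5). Its log2 fold change was -2.41 ± 0.94 (SE) and 0.32 without PBS replicate 3. Without PBS replicate 1 the neutrophil list (adjusted p = 0.00591) and the monocyte and macrophage list (0.000241) passed as higher, and without PBS replicate 3 the neutrophil list passed as lower (0.0498). The B cell and plasma cell list passed as lower without PBS replicate 2 (1.36e-08) or DOX replicate 4 (4.41e-05), and the osteoclast list without PBS replicate 2 (0.0428). The B cell and plasma cell list also passed as lower with the replicate number as a block (9.58e-09), where DOX replicates 4 and 5 add nothing to the group difference. With all libraries kept, the B cell and plasma cell list passed as lower with no batch term (0.0231). It did so too with scaling by library size alone (0.0213), no filter (0.0364) and DOX replicate 1 counted as PBS (0.0207). The collagen share as a term (0.00919) and the length and GC correction (0.00845), both chosen after seeing the data, gave the same call. The megakaryocyte and platelet list (main adjusted p = 0.521) passed as higher without PBS replicate 1 (0.00025, median 2.97) and in batch 2 alone (0.00141, median 2.62). The chondrocyte list (main adjusted p = 0.184) passed as higher without PBS replicate 1 (0.020, median 0.90) and as lower without PBS replicate 3 (0.00166, median -0.62), DOX replicate 4 (0.0385) or DOX replicate 5 (0.00239).

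**Figure D3:**
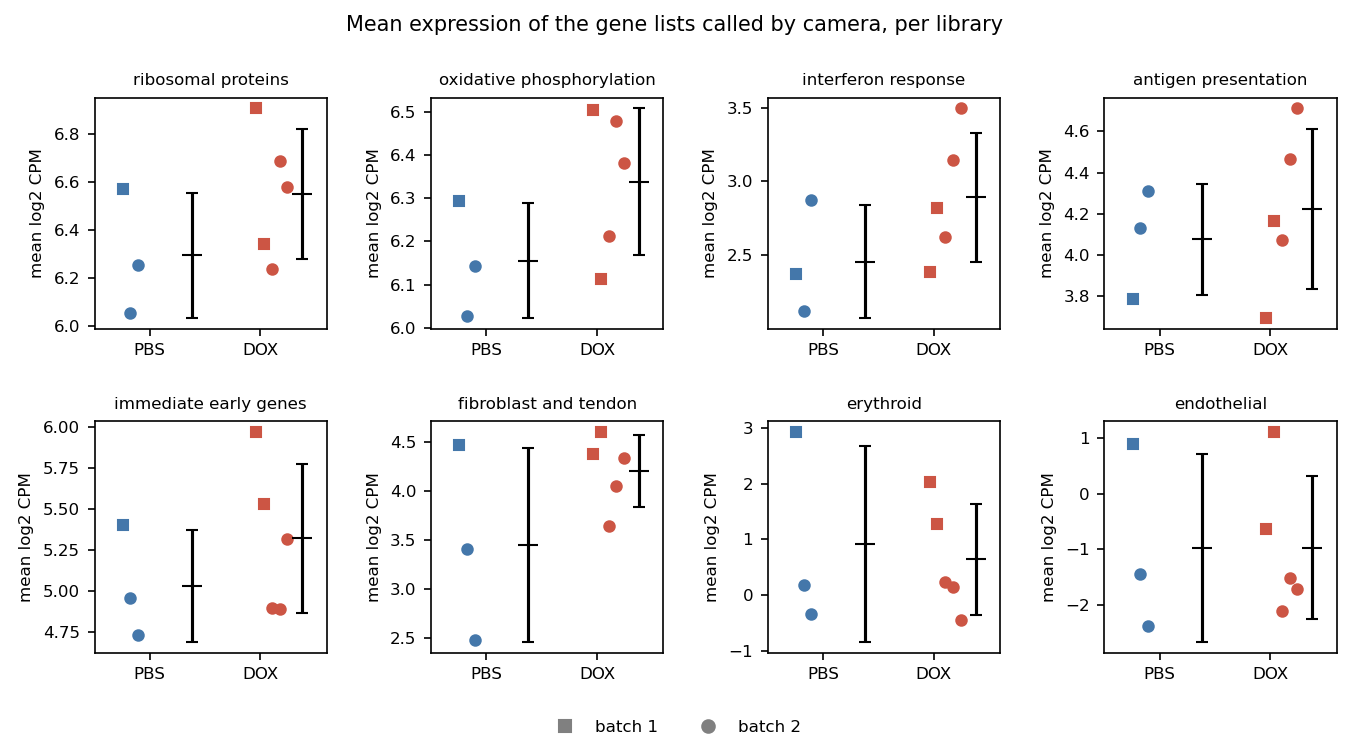
Mean log2 CPM per library of the 8 gene lists that passed in camera with the preset correlation, in PBS (n = 3) and DOX (n = 5); squares are batch 1, circles batch 2, and bars show the mean ± SD. The groups overlap in every panel, and in the erythroid panel the highest point is PBS replicate 1.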

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

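Dixon's test at the 95% level was run within the 5 DOX libraries on 129 library measures, list scores and named genes, and 12 set 1 library apart. Chance flags about 1 in 20, or 6.45 of them. DOX replicate 1, the library with conflicting labels, accounted for 7 of the 12. It had the highest hemoglobin share (0.0120% against at most 0.00283%) and the lowest lysosome and autophagy score, 5.99 log2 CPM against 6.28 to 6.36. It was also lowest for Atp5b (8.86 log2 CPM), Ldha (8.21), Lamp1 (8.97), Ctnnb1 (9.08) and Kit (1.85). DOX replicate 2 was highest for Dmp1 (10.1 log2 CPM against at most 9.38) and for Tnfsf11 (3.93 against at most 2.84). DOX replicate 3 was lowest for Cxcl12 (6.51 log2 CPM against at least 8.05) and for Vcam1 (4.37 against at least 5.49). DOX replicate 4 had the highest score of the mast cell, basophil and eosinophil list, 1.00 log2 CPM.

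The leukocyte, one-library and tendon comparisons below include choices made after the results were seen: both tests of the interferon pattern, the count of genes near 0 in PBS, the count of splits for genes called by edgeR, and the rule that set aside the tendon test. The leukocyte and muscle medians were also taken again in batch 2 alone and with each library left out, after the medians over all libraries were seen. Whether these reruns could reopen an explanation was decided after they were seen: they do for leukocytes, whose bound was written after the result, and not for muscle, whose bound was set in advance. The length and GC correction, the collagen share as a term and DESeq2 on the filtered genes were also chosen after seeing the data.

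The calls were set against the 56 ways to label 3 of the 8 libraries PBS, of which 30 keep the number of PBS libraries in each batch. For edgeR's 0 genes this decides nothing, since all 56 reach 0. The highest other grouping gave 17 genes. That grouping was batch 1 against batch 2, fitted without a batch term, which also gave 24 lists and points to a structure of the libraries. For DESeq2 on the filtered genes, 20 of 56 groupings gave at least the 15 genes of the real one, and the highest other gave 856. For lists, 55 of 56 gave at least the real 8, and the highest other gave 28. A list p as small as the real one was found in 11 of 56 groupings for ribosomal proteins (real p 1.4e-18, smallest other 1.36e-40). The number was 9 for oxidative phosphorylation (4.87e-14 and 1.68e-21), 7 for interferon response (2.52e-12 and 3.96e-26) and 7 for antigen presentation (1.41e-06 and 1.32e-16). For the other called lists it was 7 for immediate early genes, 12 for erythroid, 17 for fibroblast, periosteum and tendon, and 35 for endothelial. Among the 30 groupings that keep the batch sizes, 30 gave at least 8 lists and 11 gave at least 15 genes in DESeq2. As small a list p came from 3 of the 30 for interferon response and for antigen presentation, 4 for oxidative phosphorylation, 5 for ribosomal proteins and for immediate early genes, 7 for erythroid, 8 for fibroblast, periosteum and tendon, and 23 for endothelial. Chance could not be excluded for the DESeq2 count or any of the lists.

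The first pattern is the higher ribosomal protein and oxidative phosphorylation lists. With the share of Col1a1 and Col1a2 counts as a term in place of batch, the ribosomal list stayed higher (adjusted p = 9.72e-14 at the preset correlation). Its voom median fell from 0.23 to 0.16, and that of oxidative phosphorylation from 0.18 to 0.14, so part of the shift remained. At that correlation 55 of 56 groupings gave at least 8 lists, so the small p does not exclude collagen share as a cause. Transcript length and GC content may account for part: a correction fitted on other genes left 40.7% of the median shift of the ribosomal list and 28.2% of that of oxidative phosphorylation. Both lists still passed at the preset correlation (adjusted p = 1.66e-09 and 8e-07), so length and GC stay open as a partial cause. A response of the osteoblasts to doxorubicin also stays open, as does a chance difference between libraries.

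The second pattern is the higher interferon and antigen presentation lists. The direction of the interferon list did not rest on 1 library, though its size moved. With each library left out in turn its voom median ran from 0.24, without PBS replicate 2, to 0.53. The highest adjusted p in these fits was 0.00118. That value decides little, because camera's preset test called at least 8 lists in 55 of 56 groupings. More leukocyte RNA in the DOX libraries stays open, because the libraries disagree. Marrow was spun out and GFP-positive cells were sorted, which would remove most leukocytes, but Ighm at 393 CPM in PBS replicate 3 shows that the libraries were not free of their RNA. Over all libraries 59 leukocyte markers had a median log2 fold change of -0.10 (95% bootstrap interval -0.25 to 0.10), against 0.39 for the interferon list. In batch 2 alone the median was 0.25 (0.04 to 0.59) against 0.50, and without PBS replicate 1 it was 0.33 (0.13 to 0.67) against 0.50. These intervals resample genes and not mice, so they leave out the differences between libraries. The 59 markers also pool lists that went different ways. Of the B cell and plasma cell members 17 of 21 were lower, and of the neutrophil members 12 of 16 were higher. The T and NK cell and the monocyte and macrophage members split evenly. Some markers, such as Vcam1, are also in the reticular cell and skeletal progenitor list. The list tests hold at the preset correlation, and 7 of 56 groupings gave as small a p, so a chance difference between mice stays open beside an effect of doxorubicin.

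The third pattern is the higher Kera, Mstn, Chodl, Tnmd and Angptl7, of which Chodl (2 counts in PBS, 542 in DOX) and Tnmd were chosen after their values were seen. Of the Chodl counts in DOX, 343 came from DOX replicate 4 and 5 from DOX replicate 5. RNA from skeletal muscle was argued against by 10 muscle genes with a PBS mean under 20 CPM, whose median log2 fold change was -0.21 (95% bootstrap interval -0.53 to 0.59), and Acta1, an abundant muscle transcript also chosen after its values were seen, stood at 0.211 CPM in PBS and 0.214 in DOX. The upper bound stayed under the value of 1 set in advance in batch 2 alone (0.88, median 0.39) and with all but 1 library left out in turn. Without DOX replicate 3 it was 1.23, so the argument against muscle is weaker there. The muscle intervals, and that for tendon below, also resample genes and not mice, so they leave out the differences between libraries. RNA from tendon or periosteal cells stays open. The 16 other low members of that list had a median of 0.17 (interval 0.03 to 0.79), below the value of 1 set in advance, but that bound was wrong for a small share of cells: their median PBS level, 4.71 CPM, exceeds the median gain of the 5 genes, 3.14 CPM. The groupings were not counted for these 5 genes as a set. A separate count took the genes with at most 6 counts over PBS and at least 10 in each DOX library. They numbered 5 and are mostly other genes: Kera, Mstn, Catsperg1, Mfap4 and Rflna, the last 3 named because they met these limits. For that number, 5 of 56 groupings gave as many, with a highest other of 8, as did 2 of the 30 that keep the batch sizes. These limits were set after the counts of Mstn and Kera were seen, which favours the real grouping, and chance still could not be excluded for that number.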

How the results depend on the processing

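Alternatives chosen after seeing the data were DESeq2 on the filtered genes, leaving out PBS replicate 1 and DOX replicate 1 together, the length and GC correction, and the collagen share as a term. EdgeR called 0 genes under every setting run. DESeq2 called 26 genes on the whole table and 15 on the filtered genes, where none of the 8 lower genes had been kept by the filter. The number of lists called was 8; it was 15 in batch 2 alone, 16 without PBS replicate 1 and DOX replicate 1 together, 18 with DOX replicate 1 counted as PBS, and 10 to 16 when 1 library was left out, with 16 without PBS replicate 1. It was 0 with an estimated correlation and 0 in fry, which do not fix the correlation between genes at 0.01. The cause of the other changes was not tested. Of the 39 lists not called, 12 passed under no setting and 9 passed without PBS replicate 1. The median of the endothelial list, -0.04 in edgeR and -0.56 in voom, turned in voom to 0.051 in batch 2 alone, 0.12 without both libraries and 0.53 with DOX replicate 1 counted as PBS, and ran from -1.10 to 0.29 with 1 library left out.

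Same-numbered replicates 1, 2 and 3 correlated by 0.248, -0.05 and 0.245 in their deviations from the group means. Replicates 1 and 3 shared a batch between the groups, and replicate 2 did not. The highest value for unlike numbers was 0.178, for PBS replicate 2 and DOX replicate 3, also of the same batch. With so few pairs, whether the numbers pair the libraries cannot be decided. With the replicate block, where the group difference rests on replicates 1, 2 and 3 alone, edgeR called 0 genes and camera 11 lists. Among the values of the 70 named genes under other settings, 14 newly passed and 0 reversed a call. Without a call, 34 genes changed sign under at least 1 setting. Scaling by library size alone moved the median log2 fold change of all genes from 0.02 to 0.11. Counts under 10 over the PBS libraries limit the precision of Kera and Mstn.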

Other observations

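Immunoglobulin segments differed sharply in 1 library, and were singled out after their values were seen. Ighv11-2 had 2129 counts and Igkv14-126 had 5352 counts over the PBS libraries, all of them in PBS replicate 3, against 0 and 1 counts over the DOX libraries. Genes matched by the start of an immunoglobulin symbol, which include constant region genes such as Ighm, took 0.0740% of counts in PBS replicate 3. In any other library they took at most 0.00512%. This heavy and light chain pair is known from B-1a cells, a self-renewing B cell type.

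Of the lists not described in the report, 3 lay near the threshold in camera. The cholesterol synthesis list had 18 of 23 members lower (adjusted p = 0.053), with a score difference of -0.69 within batch 1 and 0.11 within batch 2. The canonical Wnt signalling list had 27 of 37 members lower (adjusted p = 0.053). It holds both activators and inhibitors of the pathway, so its direction does not show whether the pathway was less active. The 11 tested genes of the mitochondrial genome were all higher (adjusted p = 0.0651). None of the 3 passed in the main test, though each passed under some other setting, with an adjusted p of 0.000534 for cholesterol synthesis without PBS replicate 3, 0.0201 for Wnt signalling without DOX replicate 5 and 0.000684 for the mitochondrial genome without DOX replicate 2. The median of the mitochondrial genome, 0.19 in voom, turned negative with the length and GC correction, chosen after seeing the data (-0.09, adjusted p = 0.949), and with DOX replicate 1 counted as PBS (-0.10, adjusted p = 0.397). The length and GC correction took the Wnt median from -0.16 to -0.08 (adjusted p = 0.313) and the cholesterol synthesis median from -0.15 to -0.17 (adjusted p = 0.0556). With an estimated correlation the adjusted p of the 3 lists was 0.941, 0.904 and 0.941.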
